A study of Mus musculus with 32 samples.

How the data were processed

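Testis, spleen, liver and lung samples of NIH Swiss mice were labelled as biotinylated cRNA and hybridised to an Illumina BeadChip, 1 array per sample, 32 in all, per the labels' protocols. The deposited intensity table came from GenomeStudio, per the submitters' processing notes, whose version is not given in the sources used here. The values show that the authors had subtracted background and quantile normalized the intensities over all 32 arrays: the sorted values of the arrays departed from each other by at most 0.91, 22.0% to 22.5% lay below 0, and the highest was 24070.3. A second deposited table of non-normalized intensities repeats sample names in its header. Only 3 of its 32 signal columns could be given to samples by name, and these were used as a check: each ranked the probes as its column in the first table did (Spearman rho 1.0). The per-sample columns not used numbered 61, of which 29 held signal and 32 detection p. The planned background correction with neqc and the detection p-values were therefore replaced by the authors' values, and the organs were not normalized separately.

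Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 were unnamed in the platform annotation, and 23962 were matched to a gene of the reference table by identifier. The brightest probe over all arrays stood for each of 16593 genes, of which 4777 had more than 1 probe. Intensities were floored at 0, increased by 16 and log2-transformed. A probe counted as detected above 1.645 times the noise SD of its array, estimated from the values below 0 (threshold 8.048 or 8.292), and a gene was tested in an organ if detected in at least 2 of its 8 arrays. Signal over background, rather than a read depth, limits dim genes. Where a gene was not above background in 1 of 2 groups, a fold given as "at least" set that group no lower than its arrays' lowest detected signal. The other group entered by its measured mean without an error, so such a fold does not bound the true change.

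In each organ the 8 arrays were fitted by dose with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and each dose was contrasted with vehicle. A linear slope per 30 mg/kg was fitted separately, and the contrast of testis and spleen against liver and lung used all 32 arrays. Adjusted p-values are Benjamini-Hochberg values and calls used 0.05. Gene lists, 40 in number with 1017 genes of which 902 were on the array, were tested with camera at a preset correlation of 0.01, if at least 5 members were tested, and again with an estimated correlation. No list call at 90 mg/kg passed with an estimated correlation. The lists, groups, tests and the rule for named genes were fixed before the intensities were seen, while the offset and the detection threshold were set after. Per organ at 90 mg/kg, the rule took up to 10 rises and 10 falls among the called genes whose treated arrays both lay on one side of both vehicle arrays, and up to 4 called members of each list, or 2 members by p where none passed. It also took 5 genes each way for the contrast between organs and for the lower doses, and Cdkn1a and Isg15 in every organ. Genes with a dose trend in liver and lung were named after their values were seen. No probe named for a FACT subunit was found among the named probes, and 1719 probes were unnamed, so that comparison was not analysed here.

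The fit was tested on simulated data with known changes added to the noise of each organ: 78% of genes with a log2 change of 1 were recovered in testis, 44% in spleen, 22% in liver and 20% in lung, with 5 to 17 false calls. The simulated noise was independent between genes, and 100 genes changed at each size, so recovery in the real data may be lower. Alternatives changed the detection filter, the treatment of several probes, the arrays in the fit, the replicate number as a block and each array in turn. After seeing the data, an offset of 50, a floor in place of the offset, cyclic loess within the organ, subtraction of a testis share and leaving out 1450 testis-enriched genes were added. A testis-enriched gene had a testis vehicle mean above 100 and at least 10 times the liver mean. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.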

Results

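Gene expression was profiled in the testis, spleen, liver and lung of male NIH Swiss mice aged 7 weeks, collected 24 hours after a single intravenous dose of CBL0137 at 30, 60 or 90 mg/kg or of a vehicle of 5% dextrose. CBL0137 is a DNA-binding compound that acts on FACT, a histone chaperone, and the series set FACT positive organs beside negative ones. Each of the 16 groups of organ and dose held 2 arrays, 32 in all, on an Illumina BeadChip. The labels do not say whether the 2 arrays of a group came from separate mice, so p-values measure the spread between these arrays. The 2 arrays of a group correlated at r = 0.9745 to 0.9912 over all probes, and 54.8% to 55.6% of the 25697 probes of an array lay above the background threshold. The number of arrays limits the precision. Log2 fold changes are given ± SE on a scale of log2(signal + 16), which understates changes of dim probes. The labels do not say which organs count as FACT positive, and the levels of the FACT subunits were not analysed here.

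In the spleen at 90 mg/kg, interferon-stimulated genes rose and genes of erythroid cells and of cell division fell. Ifit3, an antiviral effector induced by interferon, rose 17.4-fold (log2 4.12 ± 0.28, adjusted p = 0.00127 in limma). Klf1, the master transcription factor of red cell development, fell by 4.12 ± 0.59 on the log2 scale (adjusted p = 0.0253). Of 11041 genes tested, 478 changed, of which 235 were higher and 243 lower, and 2757 had an unadjusted p under 0.05. Genes with testis-enriched expression made up 167 of the 243 lower genes and 4 of the 235 higher genes, against 11.8% of the genes tested.

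Of the 41 interferon-stimulated genes measured in the spleen, 30 rose at 90 mg/kg over all genes tested, and 35 rose and 1 fell adjusted over the list alone. The list's median log2 fold change was 1.80 (camera adjusted p = 3.56e-25, and adjusted p = 0.113 with an estimated correlation). Irf7, the transcription factor that amplifies the interferon response, rose by 3.79 ± 0.27, Usp18, a brake on interferon receptor signalling, by 3.78 ± 0.27, and Oas2, a sensor of double-stranded RNA, by 3.63 ± 0.24. Mx2 rose by 3.20 ± 0.17, Oasl2 by 3.00 ± 0.20 and Isg15 by 2.39 ± 0.43 (adjusted p = 0.0355). The antigen presentation and interferon-gamma list had a median of 0.61, and 3 of its 27 members rose, 10 adjusted over the list alone: Tap1, which carries peptides to class I molecules, by 1.19 ± 0.21, Igtp by 1.12 ± 0.18 and Nlrc5, the class I transactivator, by 1.09 ± 0.20. Its camera adjusted p was 0.00021, and adjusted p = 0.441 with an estimated correlation.

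Macrophage and endothelial markers were also higher in the spleen at 90 mg/kg. Of 19 macrophage markers 6 rose, and 9 rose adjusted over the list alone, with a list median of 0.69 (camera adjusted p = 0.000264, and adjusted p = 0.441 with an estimated correlation). Fcgr1, a high-affinity immunoglobulin receptor, rose by 2.29 ± 0.29, Siglec1 by 1.79 ± 0.34, and the complement genes C1qa and C1qb by 1.60 ± 0.24 and 1.29 ± 0.17. Fcgr4 and Ms4a6d, outside the lists, rose by 2.78 ± 0.34 and 2.95 ± 0.26, the collagenase gene Mmp13 by 2.94 ± 0.57 and Plek, the platelet and leukocyte protein pleckstrin, by 3.43 ± 0.54. Of 20 endothelial markers 3 rose, and 12 rose adjusted over the list alone. These were Ptprb (1.13 ± 0.25), Mmrn2 (1.03 ± 0.19) and Ramp2 (0.98 ± 0.21), and the list median was 0.80 (camera adjusted p = 1.01e-06, and adjusted p = 0.441 with an estimated correlation).

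Of 25 erythroid markers in the spleen 8 fell at 90 mg/kg, and 17 fell adjusted over the list alone, with a median of -1.97 (camera adjusted p = 1.41e-12, and adjusted p = 0.455 with an estimated correlation). Falls included Icam4, a red cell surface antigen (-2.92 ± 0.63), and Tfrc, the transferrin receptor (-2.89 ± 0.46). Other large falls, not all of erythroid genes, were those of the amino acid transporter gene Slc38a5 (-4.13 ± 0.67), Mgst3 (-3.90 ± 0.44), Abcg4 (-3.42 ± 0.49), Nxpe2 (-3.25 ± 0.48), Mns1 (-3.25 ± 0.44), Hemgn (-3.21 ± 0.58) and Asns, asparagine synthetase (-2.86 ± 0.30). They were named without setting apart testis-enriched genes, which made up 167 of the 243 lower genes. Some may therefore reflect the testis signal of the vehicle arrays given below. Of 38 proliferation genes 19 fell, and 33 fell adjusted over the list alone, with a median of -1.55 (camera adjusted p = 1.4e-21, and adjusted p = 0.441 with an estimated correlation). Among them were Birc5, a mitotic survival protein (-2.73 ± 0.42), the replication licensing factor Cdc6 (-2.73 ± 0.52), Prc1 (-2.44 ± 0.33) and the mitotic kinase gene Cdk1 (-2.37 ± 0.47). The vehicle arrays themselves lay 0.54 above and 0.54 below their mean for proliferation genes and 0.59 above and below it for erythroid markers.

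Histone genes, p53 targets and heat shock genes in the spleen moved little or in part, while germ cell markers are given below. Of 47 histone genes 6 fell and 1 rose at 90 mg/kg, and 11 fell and 4 rose adjusted over the list alone. The 4 largest changes were falls of H2A genes, H2ac11 by 2.09 ± 0.42, H2ac12 by 1.56 ± 0.24, H2ac22 by 1.56 ± 0.24 and H2ac15 by 1.53 ± 0.23. The median of that list was 0.08, its mean -0.15 and the direction of its test down (camera adjusted p = 0.267). Of 28 p53 targets 2 rose over all genes and over the list alone, Dcxr by 0.95 ± 0.19 and the cell cycle inhibitor gene Cdkn1a by 0.79 ± 0.17 (adjusted p = 0.0461), and the list median of 0.26 did not pass (camera adjusted p = 0.0798). Of 18 heat shock genes 1 fell, Dnajb1 by 1.12 ± 0.20 (median -0.31, camera adjusted p = 0.0376, and adjusted p = 0.709 with an estimated correlation, lost without vehicle replicate 2 or 90 mg/kg replicate 2).

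**Figure D1:**
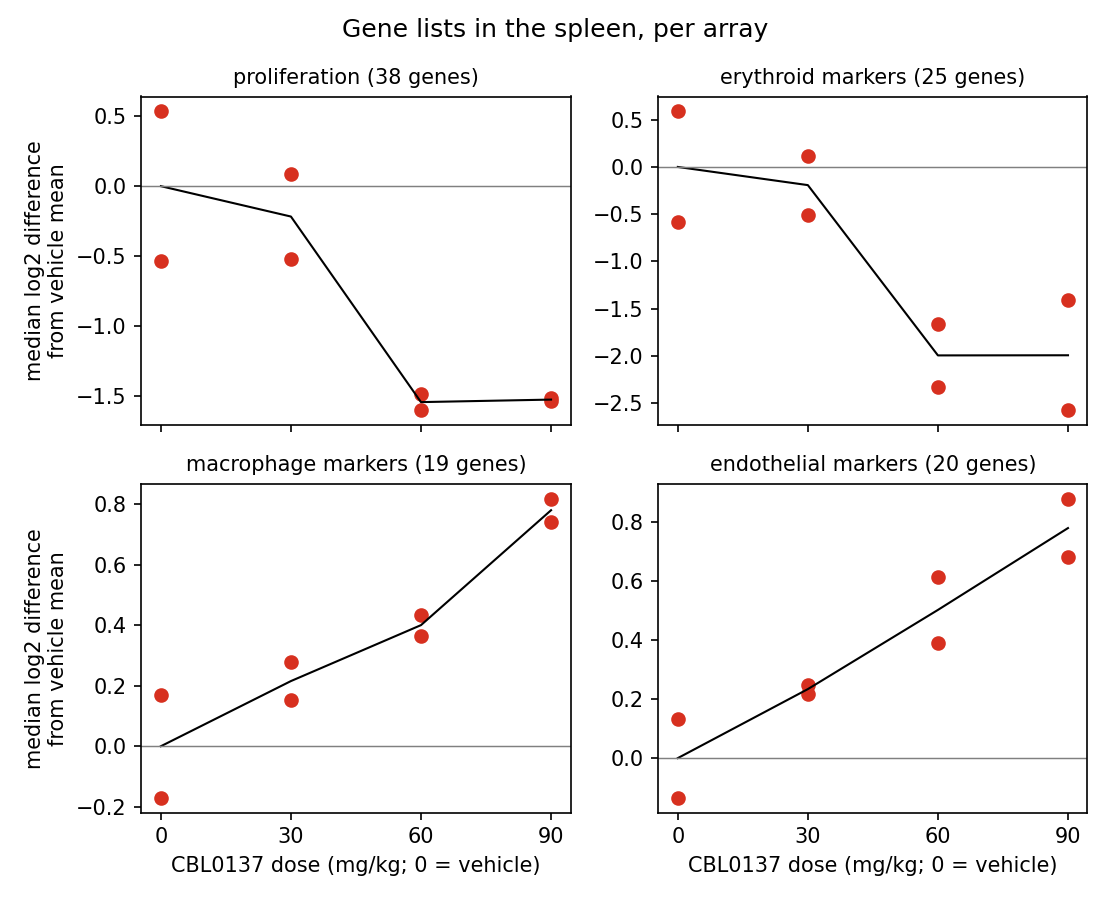
Each point is 1 spleen array and shows the median log2 difference from the vehicle mean over the genes of a list, against the dose in mg/kg, and lines join the means of the 2 arrays. Proliferation arrays lie at -1.60 and -1.49 at 60 mg/kg and at -1.54 and -1.52 at 90 mg/kg, below both vehicle arrays.

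At 60 mg/kg interferon-stimulated genes rose in the spleen, and erythroid and proliferation genes fell. Of the interferon-stimulated genes 23 rose at 60 mg/kg, and 35 rose and 1 fell adjusted over the list alone, with a median of 1.38 (camera adjusted p = 3.25e-24, and adjusted p = 0.124 with an estimated correlation). The largest rises were Plek (3.61), Ifit3 (3.50), Oas2 (3.10), Usp18 (2.98) and Irf7 (2.95), and the largest falls Klf1 (-4.54), Slc38a5 (-4.28), the red cell ankyrin Ank1 (-3.91), Mgst3 (-3.77) and Nxpe2 (-3.69). Proliferation genes had a median of -1.55, with 8 falling and 34 adjusted over the list alone (camera adjusted p = 2.15e-24, and adjusted p = 0.427 with an estimated correlation). Of the erythroid markers 7 fell, and 20 adjusted over the list alone (camera adjusted p = 1.1e-15, and adjusted p = 0.427 with an estimated correlation). At 30 mg/kg no member of these 3 lists passed, over all genes or the list alone. Interferon-stimulated genes had a median of 0.36 there (camera adjusted p = 0.000147, and adjusted p = 0.459 with an estimated correlation) and proliferation genes of -0.21 (camera adjusted p = 0.0258, and adjusted p = 0.857 with an estimated correlation), and erythroid markers did not pass (-0.16, camera adjusted p = 0.159). In total 209 genes changed at 60 mg/kg (82 higher and 127 lower, 89 of the 127 being testis-enriched) and 345 at 30 mg/kg (17 higher and 328 lower). A linear dose trend was found for 588 genes, 400 rising and 188 falling with dose. The excess of rising genes depended on the processing: cyclic loess gave 243 rising and 246 falling, and 1 fit over all 32 arrays 769 rising and 992 falling.

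Of the 328 genes that fell in the spleen at 30 mg/kg, 321 were testis-enriched, that is, far brighter in vehicle testis than in liver. The largest falls were Fabp9 (-4.80), Gsg1 (-4.68), Smcp (-4.59), a sperm mitochondrial protein, Odf1 (-4.48), a protein of the sperm tail, and Oaz3 (-4.41). The largest rises were Plek (3.01), Ccng2 (2.18), Usp38 (1.75) and Stbd1 (1.59), and Tmtc4, not above background in the vehicle arrays, was at least 3.02-fold higher. Of 27 spermatid markers 19 fell at 30 mg/kg and 25 fell adjusted over the list alone (median -3.12, camera adjusted p = 1.9e-32, and adjusted p = 0.459 with an estimated correlation). At 90 mg/kg 8 fell, among them Acrv1, Spaca3, Tekt1 and Spaca7, and 24 fell adjusted over the list alone, with a median of -2.20 (camera adjusted p = 2.68e-15, and adjusted p = 0.441 with an estimated correlation). Of 16 spermatocyte markers 2 fell at 90 mg/kg, Piwil1 by 1.77 ± 0.32 and Rec8 by 1.06 ± 0.20, and 6 fell adjusted over the list alone (median -1.06, camera adjusted p = 0.000108, and adjusted p = 0.441 with an estimated correlation). With the testis share subtracted, the median of the spermatocyte markers was -0.34 and the call ended (adjusted p = 0.183). The spermatid markers kept their call in all 16 alternatives (medians -2.66 to -1.65). The excess of 26 spermatid markers in vehicle spleen had a median of 4.66% of the testis signal and an upper quartile of 7.38%. The share over 128 testis-expressed probes was 2.66% and 5.09% in the vehicle arrays. Subtracting that share may leave part of the spermatid signal, so the kept call does not separate testis RNA from other causes.

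The 2 vehicle spleen arrays held the signal of 128 probes that are bright in testis and not detected in liver at a median of 2.66% and 5.09% of the testis level, and the treated spleen arrays at -0.0218% to 1.18%. In the lung the vehicle arrays lay at 1.05% and 0.624% and the treated arrays at 0.0115% to 0.166%. With testis-enriched genes left out, a choice made after seeing the data, 0, 89 and 296 genes changed in the spleen at 30, 60 and 90 mg/kg, the 89 being 60 higher and 29 lower and the 296 being 224 higher and 72 lower. Leaving out single arrays moved the count at 90 mg/kg to between 22 (without spleen 90 mg/kg replicate 2) and 228 (without vehicle replicate 2). It moved the count at 60 mg/kg down to 6 (without 60 mg/kg replicate 1), at 30 mg/kg down to 0 (without 30 mg/kg replicate 1) and for the trend down to 39 (without vehicle replicate 1). Without the detection filter the counts at 30, 60 and 90 mg/kg were 0, 9 and 38 (34 higher and 4 lower). With the replicate number as a block they were 0, 43 and 49 (40 higher and 9 lower). Cyclic loess gave 161 higher and 313 lower at 90 mg/kg. Over the alternatives, medians at 90 mg/kg ran from -2.04 to -0.998 for proliferation genes, 0.45 to 0.87 for macrophage markers and -0.46 to -0.19 for heat shock genes.

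**Figure D2:**
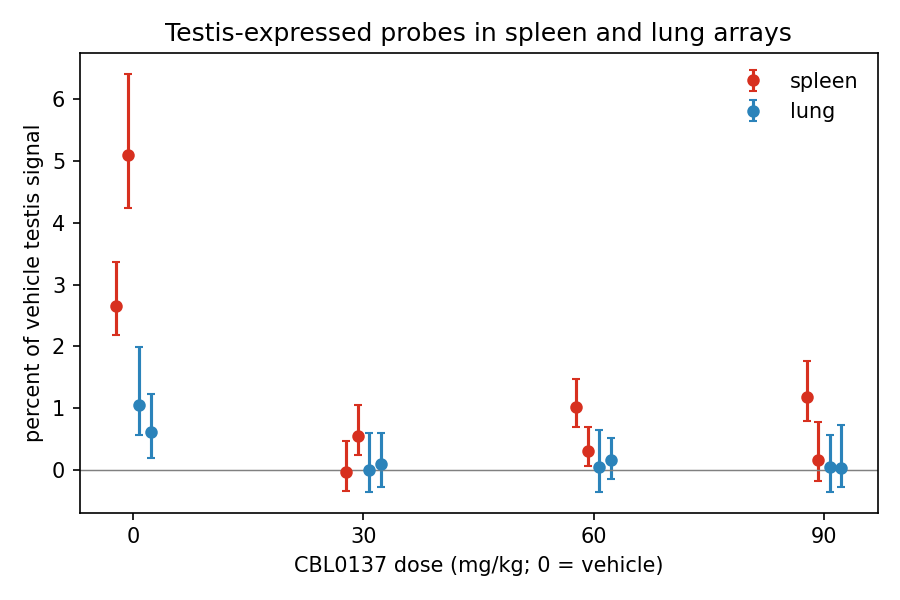
Points show, for each spleen and lung array, the median signal of 128 testis-expressed probes as a percent of their vehicle testis signal, with bars from the first to the third quartile, against the dose in mg/kg. The 2 vehicle spleen arrays lie at 2.66% and 5.09%, above all treated arrays.

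In the liver no gene changed at 30, 60 or 90 mg/kg in limma, and several lists moved together at 90 mg/kg. Usp18 was the 1 gene with a dose trend, with a slope of 1.13 per 30 mg/kg (adjusted p = 0.0183). Cdkn1a, the p53-induced cell cycle inhibitor, was 9.91-fold higher at 90 mg/kg (log2 3.31 ± 0.32, adjusted p = 0.0504), just outside the threshold, and Usp18 9.98-fold higher (3.32 ± 0.38, adjusted p = 0.0719). At an unadjusted p under 0.05, 559, 808 and 1287 of 11521 genes were found at the 3 doses.

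Interferon-stimulated genes had medians of 0.18, 0.63 and 0.72 in the liver at 30, 60 and 90 mg/kg. At 90 mg/kg none of 40 rose over all genes and 17 rose adjusted over the list alone (camera adjusted p = 2.64e-14, and adjusted p = 0.457 with an estimated correlation). Isg15 had a value of 1.19 ± 0.36 and Ifit2 of 1.73 ± 0.27. The p53 target list had a median of 0.43 with 2 of 26 rising adjusted over the list alone and none over all genes (camera adjusted p = 0.000475, and adjusted p = 0.541 with an estimated correlation), and its values included Trp53inp1 at 1.19 ± 0.26. The 42 histone genes had a median of 0.31, none passing over all genes and 4 rising adjusted over the list alone (camera adjusted p = 6.5e-06, and adjusted p = 0.647 with an estimated correlation). The members with the smallest p were H2ac8 (1.63 ± 0.34) and H1f2 (1.08 ± 0.26). Antigen presentation genes lay at 0.32, 2 of 25 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.0313, and adjusted p = 0.647 with an estimated correlation, lost in 6 of 15 alternatives).

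Genes of fatty acid synthesis had a median of -0.79 in the liver at 90 mg/kg, and 6 of 16 fell adjusted over the list alone and none over all genes (camera adjusted p = 3.84e-07, and adjusted p = 0.647 with an estimated correlation). Thrsp, which activates lipogenic genes, had a value of -2.55 ± 0.50 and Me1, malic enzyme, of -1.23 ± 0.28. Cholesterol synthesis genes had a median of -0.37 with no member passing (Mvd -1.57 ± 0.44, camera adjusted p = 0.000475, and adjusted p = 0.688 with an estimated correlation, lost in 1 of 15 alternatives). Fasting and PPAR-alpha genes had a median of -0.28, 3 of 19 falling adjusted over the list alone (G6pc -1.93 ± 0.32, Acaa1b -1.72 ± 0.28, camera adjusted p = 0.0334, and adjusted p = 0.583 with an estimated correlation, lost in 5 of 15 alternatives). Metallothioneins and oxidative stress genes lay at a median of 0.51 (Gsta2 1.20 ± 0.35, camera adjusted p = 0.00268, and adjusted p = 0.657 with an estimated correlation, lost in 2 of 15 alternatives) with no member passing. Acute phase genes lay at 0.37, 5 of 24 rising adjusted over the list alone (Lbp 1.39 ± 0.25, Orm2 1.60 ± 0.37, camera adjusted p = 0.00411, and adjusted p = 0.688 with an estimated correlation, lost in 2 of 15 alternatives). Leydig cell markers lay at 0.40 (camera adjusted p = 0.0456, and adjusted p = 0.583 with an estimated correlation), with no member passing. Their call was lost in 9 of 15 alternatives, and the median reached 0.14. B cell markers lay at -0.31 (camera adjusted p = 0.0456, and adjusted p = 0.647 with an estimated correlation, lost in 8 of 15 alternatives), with no member passing. Adipocyte genes lay at -0.40 (camera adjusted p = 0.032, and adjusted p = 0.647 with an estimated correlation, lost in 5 of 15 alternatives), also with no member passing. Over the alternatives, medians ran from 0.26 to 0.51 for p53 targets, 0.24 to 0.48 for histone genes, 0.105 to 0.43 for antigen presentation, 0.15 to 0.70 for acute phase and -0.58 to -0.17 for cholesterol synthesis. They ran from -0.41 to -0.09 for fasting genes, -0.45 to -0.12 for B cell markers and -0.56 to -0.15 for adipocyte genes. In simulated data with noise independent between genes, 22% of genes with a log2 change of 1 and 96% with a log2 change of 2 were recovered in the liver. These shares may overstate recovery in the real data, where Cdkn1a at 3.31 did not pass. One fit over all 32 arrays called 58, 112 and 398 genes at 30, 60 and 90 mg/kg. In liver 63 genes were called at 90 mg/kg with an offset of 50, and 4 at 90 mg/kg without liver 30 mg/kg replicate 1.

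In the lung no gene changed at 30, 60 or 90 mg/kg in limma, and 4 had a dose trend. Slfn1, an interferon-inducible Schlafen gene, had a slope of 0.91 per 30 mg/kg (adjusted p = 0.0117), the histone genes H4c12 and H2ac18 of 0.64 and 0.58, and Fscn1, the actin-bundling protein fascin, of -0.46 (adjusted p = 0.0377 each). At an unadjusted p under 0.05, 662, 1007 and 1294 of 11313 genes were found at 30, 60 and 90 mg/kg. The smallest adjusted p at 90 mg/kg was 0.0835.

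Interferon-stimulated genes had medians of 0.10, 0.68 and 0.94 in the lung at the 3 doses, and at 90 mg/kg 19 of 41 rose adjusted over the list alone and none over all genes (camera adjusted p = 3.24e-18, and adjusted p = 0.645 with an estimated correlation). Oasl1, not above background in the vehicle arrays, had a measured rise of at least 6.78-fold without passing over all genes. Isg15, a ubiquitin-like modifier, had a value of 2.55 ± 0.77 (adjusted p = 0.256). The p53 targets had a median of 0.22, no member passing (Cdkn1a 1.08 ± 0.37, camera adjusted p = 0.0134, and adjusted p = 0.773 with an estimated correlation, lost in 3 of 17 alternatives). Histone genes had a median of 0.52, 15 of 38 rising adjusted over the list alone and none over all genes (H4c18 1.87 ± 0.23, H4c12 1.80 ± 0.20, camera adjusted p = 2.22e-09, and adjusted p = 0.645 with an estimated correlation). At 30 mg/kg the direction of the histone list was down, with a median of -0.23 (camera adjusted p = 0.00495, and adjusted p = 0.77 with an estimated correlation). Proliferation genes had a median of -0.52, 11 of 31 falling adjusted over the list alone (Prc1 -1.72 ± 0.23, Cdca3 -1.60 ± 0.36, camera adjusted p = 4.95e-08, and adjusted p = 0.645 with an estimated correlation). Glucocorticoid-induced genes had a median of 0.48, 3 of 14 rising adjusted over the list alone (Fkbp5 2.26 ± 0.41, camera adjusted p = 0.000485, and adjusted p = 0.773 with an estimated correlation, lost without vehicle replicate 1). Neutrophil markers lay at 0.88 (Retnlg 3.10 ± 0.85, camera adjusted p = 0.00334, and adjusted p = 0.773 with an estimated correlation), with no member passing. Their call was lost without vehicle replicate 2 and without the detection filter, and the median ranged from 0.19 to 1.14. Erythroid markers lay at -0.46, 3 of 22 falling adjusted over the list alone (Slc4a1 -3.05 ± 0.57, camera adjusted p = 0.00052, and adjusted p = 0.773 with an estimated correlation, lost without vehicle replicate 1). Several of these lists had moved already at 30 mg/kg. Proliferation genes lay there at -0.545 (camera adjusted p = 5.56e-09, and adjusted p = 0.343 with an estimated correlation). Erythroid markers lay at -0.36 and glucocorticoid-induced genes at 0.39 (camera adjusted p = 8.48e-05 each, and adjusted p = 0.704 and 0.77 with an estimated correlation).

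Spermatid markers had a median of -1.26 in the lung at 90 mg/kg, 22 of 26 falling adjusted over the list alone and none over all genes (camera adjusted p = 1.04e-20, and adjusted p = 0.645 with an estimated correlation), beside the testis signal of the vehicle arrays given above. At 30 mg/kg their median was -1.29 (camera adjusted p = 1.17e-24, and adjusted p = 0.343 with an estimated correlation). With the testis share subtracted their median at 90 mg/kg was -0.41 (adjusted p = 6.75e-05), and with an offset of 50 it was -0.71. Spermatocyte markers lay at -0.46, 4 of 12 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.762 with an estimated correlation). Their call was lost in 3 of 16 alternatives, among them subtraction of the testis share (median -0.05, adjusted p = 0.867). No member passed among fibroblast markers (-0.38, camera adjusted p = 0.00334, and adjusted p = 0.773 with an estimated correlation, lost in 1 of 17 alternatives), B cell markers (-0.53, camera adjusted p = 0.0437, and adjusted p = 0.841 with an estimated correlation, lost in 7 of 17) or heat shock genes (-0.22, camera adjusted p = 0.0375, and adjusted p = 0.841 with an estimated correlation, lost in 3 of 17). Hepatocyte markers differed between arrays of one group: the vehicle arrays lay 1.21 below and 1.21 above their mean, and the 90 mg/kg arrays 1.25 above and 1.97 below it. Over the alternatives, medians ran from 0.26 to 0.67 for histone genes, -0.72 to -0.30 for proliferation genes, 0.23 to 0.73 for glucocorticoid-induced genes and -0.55 to -0.16 for erythroid markers. They ran from -0.89 to -0.09 for B cell markers, -0.29 to -0.11 for heat shock genes and -0.44 to -0.23 for fibroblast markers. In simulated data with noise independent between genes, 20% of genes with a log2 change of 1 and 97% with a log2 change of 2 were recovered in the lung. These shares may overstate recovery in the real data. One fit over all 32 arrays called 4, 38 and 235 genes at 30, 60 and 90 mg/kg, and the trend count fell to 0 without vehicle replicate 2.

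In the testis 1 gene changed, Thap4, a THAP family protein with a heme-binding nitrobindin domain, which rose 3.86-fold at 90 mg/kg (log2 1.95 ± 0.18, adjusted p = 0.0245), while its values were -0.09 at 60 and -0.02 at 30 mg/kg. No gene changed at 30 or 60 mg/kg, and none had a dose trend in limma. At an unadjusted p under 0.05, 4.5%, 9.07% and 7.61% of 10747 genes were found at 30, 60 and 90 mg/kg. Interferon-stimulated genes had medians of -0.01, 0.14 and 0.38 at the 3 doses, and at 90 mg/kg 1 of 30 rose adjusted over the list alone and none over all genes (camera adjusted p = 1.12e-05, and adjusted p = 0.83 with an estimated correlation). The call ended without the detection filter (median 0.20, adjusted p = 0.0573), and the median was 0.22 without 90 mg/kg replicate 2 (adjusted p = 0.0478) and 0.23 with an offset of 50. Usp18 had a value of 1.19 ± 0.21 and Ifit2 of 0.99 ± 0.32. Isg15, not above background in the vehicle arrays, had a measured rise of at least 2.19-fold without passing.

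Histone genes had a median of 0.32 in the testis at 90 mg/kg, with no member passing over all genes or the list alone (H2bc14 0.50 ± 0.19, camera adjusted p = 5.62e-05, and adjusted p = 0.83 with an estimated correlation). That call was lost without the detection filter and without vehicle replicate 1, and the median ran from 0.07 to 0.51. Antigen presentation genes lay at 0.27 (camera adjusted p = 0.00469, and adjusted p = 0.83 with an estimated correlation, lost in 3 of 15 alternatives), where Tap1 was not above background in the vehicle arrays. Circadian clock genes lay at -0.32, 1 of 14 falling adjusted over the list alone (Per2 -0.87 ± 0.18, Per1 -0.57 ± 0.25, camera adjusted p = 0.0141, and adjusted p = 0.83 with an estimated correlation, lost in 3 of 15 alternatives). Hepatocyte markers lay at 0.48 (Apoa2 1.20 ± 0.66, camera adjusted p = 0.0209, and adjusted p = 0.83 with an estimated correlation), with no member passing over all genes or the list alone. The hepatocyte call was lost in 7 of 15 alternatives. Over these, medians ran from 0.27 to 0.72 for hepatocyte markers, 0.12 to 0.37 for antigen presentation and -0.41 to -0.14 for clock genes. Spermatid and spermatocyte markers had medians of 0.02 and -0.02. Cdkn1a had a value of -0.02 ± 0.22. The call of Thap4 ended without the detection filter (adjusted p = 0.341), in 1 fit over all 32 arrays (adjusted p = 0.629), with the floor in place of the offset (adjusted p = 0.246) and with the replicate number as a block. It also ended in 6 of 8 fits with 1 array left out.

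**Figure D3:**
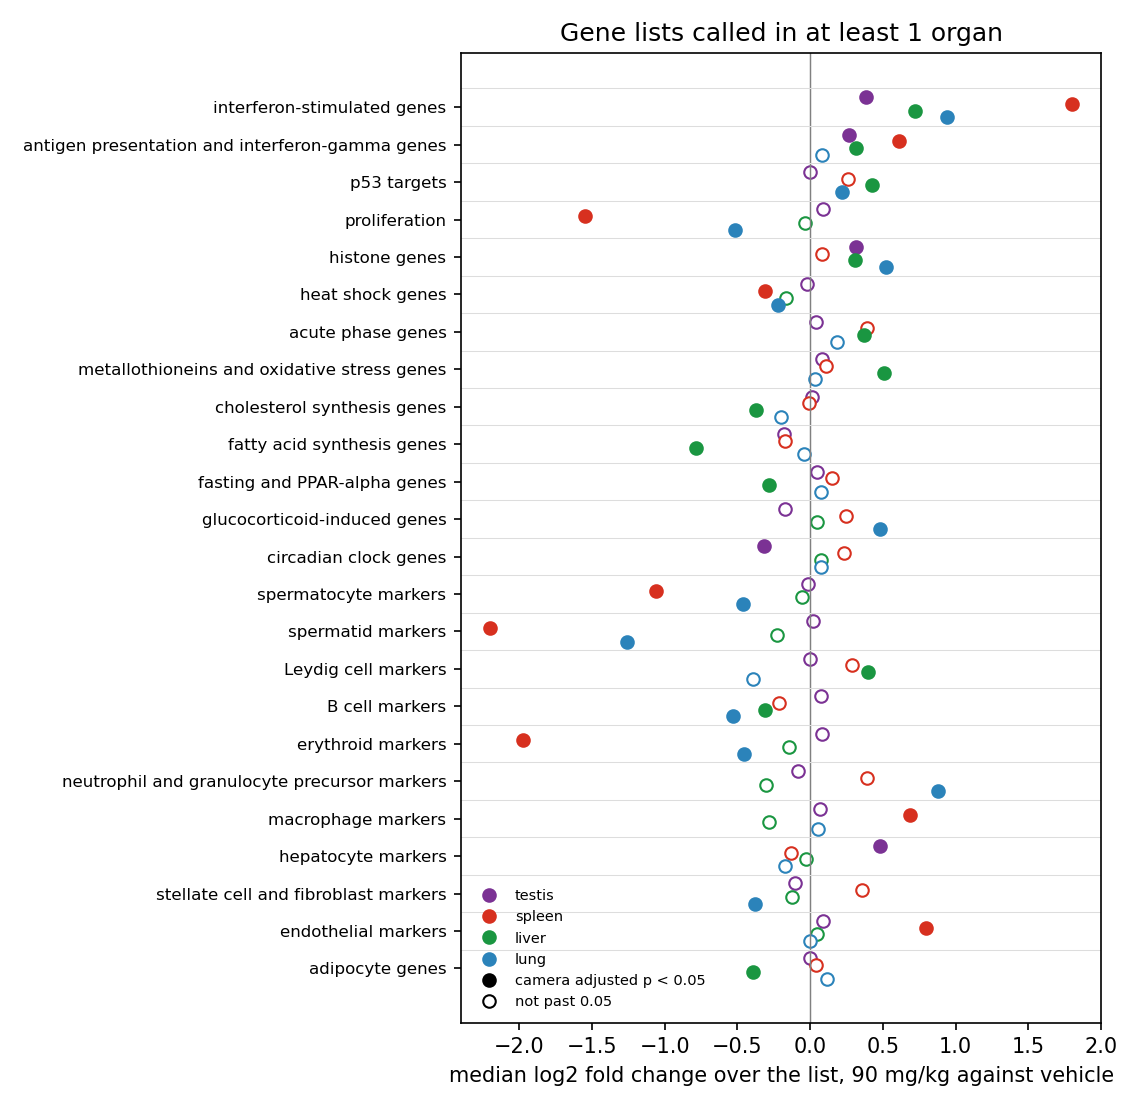
Points show the median log2 fold change at 90 mg/kg against vehicle over each list called in at least 1 organ, coloured by organ, filled where the camera adjusted p passed 0.05 and open where it did not. Interferon-stimulated genes lie at 0.38 in testis, 1.80 in spleen, 0.72 in liver and 0.94 in lung.

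To compare testis and spleen with liver and lung, the 2 mean responses at 90 mg/kg were contrasted in 1 fit of all arrays over 8518 genes detected in all 4 organs. In the same fit, 298 genes differed between testis and spleen, 588 between spleen and liver and 100 between spleen and lung. Between testis and liver 41 differed, between liver and lung 37, and between testis and lung 0. The pooled organs were thus unlike each other in these values. Counts with the spleen may include genes of the testis signal in its vehicle arrays. Spermatid markers differed by 2.22 for testis minus spleen (camera adjusted p = 7.59e-14, and adjusted p = 0.197 with an estimated correlation). The counts between pairs were not repeated with that signal removed. The interferon list did not differ in the pooled contrast (median difference 0.01, camera adjusted p = 0.943). Cdkn1a was lower in testis and spleen than in liver and lung by 1.81 ± 0.30 (difference -1.81, adjusted p = 0.0116), with log2 fold changes of -0.02, 0.79, 3.31 and 1.08 in testis, spleen, liver and lung. Positive differences were largest for Mfsd2a, a transporter of lysolipids (2.18 ± 0.41), the water channel gene Aqp8 (2.04 ± 0.41), the phospholipid transfer protein gene Pltp (1.58 ± 0.32), Aacs (1.55 ± 0.31) and Ccnd1, cyclin D1 (1.49 ± 0.32). Mfsd2a had a value of -2.99 in liver and -1.25 in lung, and Aqp8 of -3.27 in liver. Aacs and Pltp lay at -2.51 and -1.57 in liver but at -0.52 and -0.18 in lung. Negative differences were largest for Abcg4 (-2.13 ± 0.37), Tfrc (-1.89 ± 0.37), Cdkn1a, Galntl5 (-1.44 ± 0.32) and Gtse1 (-1.18 ± 0.24). Abcg4 and Tfrc had fold changes of -3.42 and -2.89 in spleen, and Galntl5, not above background in the treated spleen, was at least 11.3-fold lower there. With the testis share subtracted, the difference of Galntl5 was -0.93 and its call ended (adjusted p = 0.153).

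The contrast was significant for 44 genes, 22 with a higher and 22 with a lower response in testis and spleen, and 1263 had an unadjusted p under 0.05. Lists that differed were histone genes (median difference -0.39), proliferation genes (-0.46), erythroid markers (-0.65), p53 targets (-0.15), endothelial markers (0.36) and fibroblast markers (0.45), with camera adjusted p values of 8.68e-08, 1.85e-06, 0.00184, 0.0298, 0.00184 and 0.0298, and for each adjusted p = 0.618 with an estimated correlation. The spleen, not the testis, carried the differences in proliferation, erythroid and endothelial genes, with medians of -1.55, -1.97 and 0.80 in spleen and 0.09, 0.08 and 0.09 in testis. For p53 targets the testis lay below liver (-0.36) and lung (-0.18), with camera adjusted p = 0.00682 and 0.0152, and adjusted p = 0.714 and 0.453 with an estimated correlation. The spleen did not differ in p53 targets from liver (-0.08, camera adjusted p = 0.243) or lung (0.02, camera adjusted p = 0.716). Against lung, the testis response lay higher for proliferation genes (0.56, camera adjusted p = 9.44e-06, and adjusted p = 0.563 with an estimated correlation) and for erythroid markers (0.54, camera adjusted p = 0.0103, and adjusted p = 0.563 with an estimated correlation), opposite to the pooled sign. Leaving out single arrays moved the count to between 7 (without testis 90 mg/kg replicate 1) and 111 (without spleen vehicle replicate 2), and it was 90 with an offset of 50 and 69 with cyclic loess within the organ.

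The response of interferon-stimulated genes was also set against each other between pairs of organs, a comparison chosen after seeing the data. Over 30 genes detected in all 4 organs, the spleen exceeded the testis by a median of 1.54 (difference of testis minus spleen -1.54, camera adjusted p = 1.42e-12, and adjusted p = 0.197 with an estimated correlation). It also exceeded the liver by 0.93 (camera adjusted p = 0.00011, and adjusted p = 0.599 with an estimated correlation) and the lung by 0.66 (camera adjusted p = 0.00118, and adjusted p = 0.756 with an estimated correlation). The testis lay below the liver (-0.38, camera adjusted p = 0.00421, and adjusted p = 0.924 with an estimated correlation) and the lung (-0.64, camera adjusted p = 2.73e-08, and adjusted p = 0.453 with an estimated correlation). The liver and the lung differed by -0.30, which did not pass (camera adjusted p = 0.272).

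**Figure D4:**
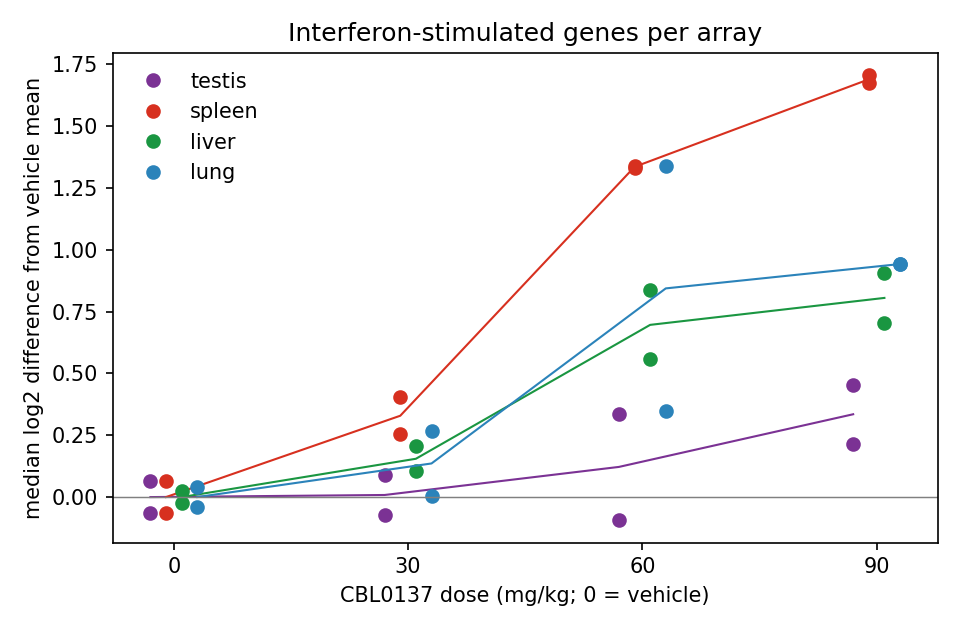
Each point is 1 array and shows the median log2 difference of the interferon-stimulated genes from the vehicle mean of its organ, against the dose in mg/kg, and lines join the means of the 2 arrays. Both spleen arrays at 90 mg/kg lie at 1.67 and 1.71, and both lung arrays at 0.94.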

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

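The tests of testis RNA by correlation, of erythroid precursors and of macrophages were chosen after the result was seen, as were the alternatives with a testis share subtracted or a floor. The other tests were written after the patterns but before their own values were seen. Responses that differed between organs, by a test of the difference itself, were the 44 genes of the contrast of testis and spleen against liver and lung, among them Mfsd2a (2.18), Aqp8 (2.04), Pltp (1.58), Aacs (1.55), Ccnd1 (1.49), Abcg4 (-2.13), Tfrc (-1.89), Cdkn1a (-1.81), Galntl5 (-1.44) and Gtse1 (-1.18). In the same contrast, lists differed for p53 targets (-0.15), proliferation (-0.46), histone genes (-0.39), erythroid markers (-0.65), fibroblast markers (0.45) and endothelial markers (0.36), each with adjusted p = 0.618 with an estimated correlation. For proliferation (0.56) and erythroid markers (0.54), the testis response lay above that of lung, against the pooled sign. Interferon-stimulated genes differed between testis and spleen (-1.54), testis and liver (-0.38), testis and lung (-0.64), spleen and liver (0.93) and spleen and lung (0.66), first organ minus second. None of these 5 passed with an estimated correlation (adjusted p = 0.197, 0.924, 0.453, 0.599 and 0.756). With the testis share subtracted, the difference of Galntl5 was -0.93 and no longer passed (adjusted p = 0.153), from adjusted p = 0.0387. Gene by gene, testis and spleen also differed from each other at 298 genes, and testis and lung at 0. The 298 may include genes of the testis signal in vehicle spleen.

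Testis-expressed genes were lower in treated than in vehicle spleen. Testis RNA in the vehicle spleen arrays is a candidate explanation: across 128 probes, which are not independent replicates, the vehicle spleen signal followed the testis signal with a Spearman rho of at least 0.837. Subtraction of the testis share ended the spermatocyte call at 90 mg/kg (median -0.34, camera adjusted p = 0.183). The spermatid markers kept their call in all 16 alternatives, that subtraction among them (medians -2.66 to -1.65). The spermatid excess in vehicle spleen had an upper quartile of 7.38% of the testis signal, above the shares of 2.66% and 5.09%. Subtraction may thus leave spermatid signal, and the kept call does not decide the question. Activity of germ cell genes in spleen cells, ended by the compound, stays open. Among treated spleen arrays the share did not fall with dose. It was -0.0218% and 0.561% at 30 mg/kg, 1.02% and 0.309% at 60 mg/kg, and 1.18% and 0.171% at 90 mg/kg. The vehicle lung arrays also followed the testis signal, with a Spearman rho of 0.441 and 0.432. These values rest on single arrays and do not decide the question. The excess in vehicle spleen per unit of testis signal was 0.426 times as high for 16 Sertoli and Leydig markers as for 26 spermatid markers, with a 95% bootstrap interval of -0.289 to 0.816. Bootstrap intervals here and below resampled genes, not arrays, so they do not measure the spread between arrays.

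Proliferation and erythroid markers were lower in spleen at 90 mg/kg. Testis RNA in the vehicle arrays is argued against as the whole cause: after its share was subtracted, the medians stayed at -1.51 (95% bootstrap interval -1.64 to -1.29) for proliferation and -1.97 (-2.79 to -1.06) for erythroid markers. Before subtraction they were -1.55 and -1.97. Members of these lists were correlated (estimates of 0.75 and 0.69), so the intervals over genes do not show the spread between arrays. A lower share of dividing erythroid precursors stays open. The erythroid median of -1.97 (-2.78 to -1.07) lay under the lower first quartile of the B and T cell lists (-0.33), but this was already visible when that comparison was chosen, so it does not test the share. Loss of cells and lower transcription within cells were not separated by any test.

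Interferon-stimulated genes were higher in spleen than in testis at 90 mg/kg. Compression by the offset itself is argued against, since with a floor in its place the median difference over 30 genes was 1.51 (1.04 to 2.05). The floor also flattens signals under 8.292, so compression of changes near background in testis was not excluded. More macrophages in the treated spleen stay open. The interferon median of 1.80 (1.38 to 2.12) lay above the third quartile of the macrophage list, 1.12, but this was already visible when that comparison was chosen, so it does not test the share. A stronger response of spleen cells and a different reach of the compound were not tested.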

How the results depend on the processing

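The offset, floor, loess and testis alternatives were chosen after seeing the data, the others before. With an estimated correlation, no list call at 90 mg/kg passed in any organ. The alternatives that follow all used the preset correlation of 0.01. In them the interferon list kept its direction and call in spleen, liver and lung throughout and in testis in all but 1: without the detection filter its median there was 0.20 (camera adjusted p = 0.0573). In spleen, the proliferation, erythroid, macrophage, endothelial and antigen presentation lists kept their calls in all 17 alternatives, as did the p53, histone and fatty acid synthesis lists in liver in all 15. Calls were lost most often for Leydig cell markers (9 of 15) and B cell markers (8 of 15) in liver, hepatocyte markers in testis (7 of 15) and B cell markers in lung (7 of 17). Where a count moved, the cause was not tested. A lone array left in a group is assumed to vary like the other groups. Signal over background limits dim genes.

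Without the detection filter, genes changed numbered 0 in testis at 90 mg/kg, 0, 9 and 38 in spleen at 30, 60 and 90 mg/kg, and 0 for the liver trend. With the mean of probes, 3 liver genes changed at 90 mg/kg and 0 had a trend. One fit over all 32 arrays gave 0 in testis at 90 mg/kg, 630, 1293 and 1587 in spleen and 1761 for its trend, 58, 112 and 398 in liver and 463 for its trend, and 4, 38 and 235 in lung and 311 for its trend. An offset of 50 gave 2 in testis at 90 mg/kg, 637 and 933 in spleen at 60 and 90 mg/kg, 3 and 63 in liver at 60 and 90 mg/kg, 141 and 9 for the liver and lung trends, and 90 between organs. The floor gave 0 in testis at 90 mg/kg, 33 in spleen at 30 mg/kg, and 0 and 1 for the liver and lung trends. Cyclic loess gave 3 in liver at 90 mg/kg and 69 between organs, and in spleen at 60 and 90 mg/kg moved the higher share of calls from 39.2% and 49.2% to 23.1% and 34%. Subtracting the testis share gave 57 in spleen at 30 mg/kg, and 67.1% higher at 90 mg/kg. Leaving out testis-enriched genes gave 0, 89 and 296 in spleen, and the 296 were all among the 478.

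The labels do not say whether the replicate numbers pair the samples. Correlations of the differences between replicates 1 and 2 ran from -0.232 to 0.403 between doses within an organ. Between organs they ran from -0.296 to 0.23. At 60 mg/kg 3 of 6 organ pairs lay above 0.1, against 0, 1 and 1 at 0, 30 and 90 mg/kg. Each difference rests on 2 arrays and no known pair was at hand, so these values do not settle the pairing. With the replicate number as a block, 0 genes changed in testis at 90 mg/kg, 0, 43 and 49 (40 higher and 9 lower) in spleen at 30, 60 and 90 mg/kg, and 328, 3 and 1 had a trend in spleen, liver and lung. Between organs the block was another one: arrays of the same dose and replicate number were allowed to correlate. That correlation was estimated at -0.000529, so the fit was nearly the main one. Its 44 genes are therefore no separate check.

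Leaving out each array in turn gave in testis 0 to 5 genes at 30 mg/kg, 0 to 1 at 60 and 0 to 1 at 90 mg/kg, with 0 for the trend. At 90 mg/kg, 2 of the 4 fits with a call did not call Thap4. In spleen it gave 0 to 334, 6 to 231 and 22 to 228, and 39 to 433 for the trend. In liver it gave 0 at 30 and 60 mg/kg, 0 to 4 at 90 mg/kg and 0 to 4 for the trend, in lung 0, 0, 0 to 2 and 0 to 2, and between organs 7 to 111. Interferon medians ran from 0.22 to 0.45 in testis, 1.58 to 1.80 in spleen, 0.64 to 0.91 in liver and 0.93 to 0.94 in lung. Directions reversed for 3 lists: histone genes in spleen (-0.17 to 0.13, and -0.02 without vehicle replicate 2), hepatocyte markers in lung (-1.97 to 1.25, and 0.73 without vehicle replicate 2) and drug metabolism genes in lung (-0.56 to 0.59). The background alternatives on raw signals, neqc over all arrays and the slide block were not run, because most raw columns could not be given to samples and no slide was named, and the authors' values were already the ones analysed.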

Other observations

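The spleen at 90 mg/kg also held single called members of lists that did not pass as a whole. The glucocorticoid-induced genes Fkbp5 and Mertk rose by 1.89 ± 0.34 and 1.08 ± 0.17, 2 of 14 members over all genes and 3 adjusted over the list alone, and the clock output genes Dbp and Nr1d2 rose by 1.17 ± 0.21 and 1.00 ± 0.22. Fcer2a, the low-affinity IgE receptor of B cells, fell by 1.12 ± 0.24, the 1 of 20 B cell markers to pass. Timp1 rose by 1.14 ± 0.23 and Il1rn, the interleukin-1 receptor antagonist, by 1.09 ± 0.22. Hmox1, which degrades heme, had a value of 1.89 ± 0.46 without passing (adjusted p = 0.0554).

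Hepatocyte markers varied between arrays of one group in lung and testis. In the testis at 90 mg/kg their median lay 0.72 above the vehicle mean in replicate 1 and 0.34 above it in replicate 2, and the list also passed at 30 mg/kg (median 0.98, camera adjusted p = 1.81e-06, and adjusted p = 0.586 with an estimated correlation). At 30 mg/kg acute phase and drug metabolism genes passed in testis too (medians 0.385 and 0.365, camera adjusted p = 0.0107 and 0.0106). With an estimated correlation neither did (adjusted p = 0.586 each). In spleen the hepatocyte list lay at 0.43, 0.58 and -0.13 at 30, 60 and 90 mg/kg (camera adjusted p = 0.0106, 0.00194 and 0.734). With an estimated correlation its adjusted p was 0.852, 0.506 and 0.913. The cause of these shifts was not tested.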
